A study of Mus musculus with 9 samples.

How the data were processed

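Gene expression was measured by RNA sequencing. Per the labels' protocols, total RNA was extracted from bone marrow-derived macrophages of C57BL6 mice with TRIzol and made into libraries with the NEBNext Ultra RNA kit. Whether the kit marked strand and how messenger RNA was selected were not given in the sources used here. The 9 libraries fell into 3 groups of 3 by their labels: untreated (PBS), Pam3CSK4, and Pam3CSK4 plus 3SL, all after 6 h. The labels state 100 µg/ml of Pam3CSK4 and 100 µl/ml of 3SL, the latter as a volume and therefore without a known amount. The titles of the 3SL libraries write Pamc4, and their treatment tag Pamc4-CSL, where their descriptions name Pam3CSK4 and 3SL. The descriptions were followed, and whether CSL and 3SL are the same compound is not stated. The untreated libraries carry the codes A2, B2 and C2, the Pam3CSK4 libraries D1, D2 and D3, and the 3SL libraries A2plus, B2plus and C2plus. The labels do not say that the 3 libraries of a group came from separate cultures or animals, so all p-values measure only the spread between these samples, which may be technical.

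The values used were raw counts per gene, as deposited by the authors in 1 table for the whole series. Per the submitters' processing notes, HISAT2 2.1.0, featureCounts and Subread were named, without a role, an order or parameters for each. The same notes name the human genome build hg38, while all 22001 gene identifiers in the table are mouse Ensembl identifiers, so the build behind the deposited counts is not settled. The annotation release and the strand setting of the counting were not given in the sources used here, and reads from a gene and an antisense or overlapping partner cannot be told apart. The table holds 15 further columns of other samples, which were not used here. Every column used held whole numbers and no line lacked a gene identifier.

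Gene symbols came from a table that pairs Ensembl identifiers with names, which named 21909 identifiers and left 92 without a symbol. Of all identifiers, 21715 were protein-coding in GENCODE release M21, and 5264 had no count in any of the 9 libraries. Coordinates are those of GENCODE M21 on the mouse build GRCm38, 1-based, and were used only to describe genes; they are not the authors' coordinates.

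Total counts per library were 17053407, 43980309 and 10203040 for A2, B2 and C2, 10954186, 15259545 and 11394651 for D1, D2 and D3, and 7472482, 10821146 and 10431427 for A2plus, B2plus and C2plus. At these depths a gene with 3 counts stands at between 0.0746 and 0.422 CPM, which is the level below which a single library cannot tell a low gene from an absent one. Intervals and floors cover counting error only, since the reads carry no molecular identifiers.

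Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the groups, which left 11469 genes (52.1%), library sizes were scaled with TMM factors, and 1 model with a mean per group was fitted to all 9 libraries, so that the 3 groups share an estimate of the spread. Each pair of groups was compared with edgeR's quasi-likelihood test, and p-values were adjusted over all tested genes by the Benjamini-Hochberg method with a threshold of 0.05 and no minimum fold. The common dispersion was 0.00133, a biological coefficient of variation of 0.0365. Levels are given as CPM, counts relative to the TMM-scaled library size, as mean ± SD over the 3 libraries of a group. Fold changes of genes with 1 to 3 counts in a whole group depend on the small prior count that edgeR adds in fitting, and for those the ratio's exact 95% counting interval is given in place of the fitted fold.

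There were 25 gene lists, covering inflammatory, interferon, lipid, metabolic, stress, cell cycle, sialic acid and lysosome genes, markers of macrophages and of other cell types, and mitochondrially encoded messenger RNAs. Each was tested with camera from limma 3.58.1, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 25 lists, and again with a correlation estimated from the data and with fry, which asks whether a list's genes move on balance one way and makes no comparison with other genes. The calls of single genes in a list were also adjusted over the list alone. The lists, tests and alternatives were fixed before the data were examined, except where another origin is stated.

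Genes were named by a fixed rule. It took, per comparison, the 8 genes with the largest rise and the 8 with the largest fall among called genes with a mean log2 CPM of at least 2 and no overlap between groups, leaving out unnamed models and mitochondrial genes. It added the 2 members with the smallest p of each list that is not a marker or RNA quality list, and Tnf, Il1b, Il6, Ccl2, Nos2, Abca1, Mylip and Tlr2. For the 3SL-labelled against the untreated-labelled libraries the rule took only the 4 largest rises and 4 largest falls. Its other parts were applied there after the values had been seen, and list members named outside the rule were likewise chosen after their values were seen. The values of 2 list members are not reported here, and both stay in the tests and counts.

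The alternatives were DESeq2 size factors (RLE), library size only, no filter on low counts, at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, robust quasi-likelihood, a fit to only the 2 groups compared, an adjusted p threshold of 0.01, leaving out each library in turn, and the letter of the library code as a replicate block. Added after the data had been seen were thinning every library to the shallowest total, offsets for GC content and transcript length (known for 99.9% of the tested genes), and a second pair of comparisons that share libraries. Comparisons sharing libraries were set beside 20 simulated draws with no effect, and 20 with the 3SL-labelled libraries drawn at the level of the shared group. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 handled tables, the chi-square comparison of libraries and plots.

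The fit was tested on counts drawn at the real depths from each gene's mean over all libraries, with 50 genes changed at each of 4 fold sizes. All other genes were equal between groups, so the rates do not cover comparisons in which most genes differ. For Pam3CSK4 against untreated, on 11390 genes, it recovered 70% of 1.25-fold, 84% of 1.5-fold, 96% of 2-fold and 96% of 4-fold changes. Of its 188 calls there, 15 were false. For 3SL against Pam3CSK4, on 11405 genes, the shares were 62%, 72%, 90% and 96%, with 6 false among 166 calls. For 3SL against untreated, on 11396 genes, they were 46%, 82%, 90% and 100%, with 9 false among 168 calls. With 24-gene lists raised 1.3-fold in simulated counts, camera called 20 of 20 raised and 0 of 20 unchanged lists in each comparison, with both correlations, on 11392, 11399 and 11397 genes. The simulated genes were drawn independently, so this does not test lists whose genes move together. The cytokine list had an estimated correlation of 0.790 for Pam3CSK4 against untreated.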

Results

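RNA sequencing measured the transcripts of mouse bone marrow-derived macrophages, phagocytes grown in culture from bone marrow precursors, after 6 h in 3 conditions: untreated, with Pam3CSK4, or with Pam3CSK4 plus 3SL. Pam3CSK4 is a synthetic triacylated lipopeptide that activates Toll-like receptors, and 3SL is taken, from the name in the series title, to be 3'-sialyllactose, an oligosaccharide of milk. There were 3 libraries per group, and 3 comparisons follow from the design: what Pam3CSK4 changed, what 3SL changed in the presence of Pam3CSK4, and how the cells with both differed from untreated cells. Total counts per library ran from 7472482 to 43980309. Libraries of a group differed by more than sampling noise, with a chi-square per degree of freedom between 1.85 and 3.01, so none was taken for a second deposit of another. This does not show that they came from separate cultures.

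The inflammatory genes did not follow the labels. Il1b, which encodes the cytokine interleukin-1 beta, stood at 10160 ± 457 CPM (SD, n = 3) in the libraries labelled untreated and at 8136 ± 565 CPM (SD, n = 3) in those labelled Pam3CSK4 plus 3SL. In the libraries labelled Pam3CSK4 it stood at 6.23 ± 1.68 CPM (SD, n = 3). Groups are therefore called untreated-labelled, Pam3CSK4-labelled and 3SL-labelled throughout, and every direction and the meaning of every comparison rest on those labels. The first principal component held 90.4% of the variance and separated the Pam3CSK4-labelled libraries from the other 6. The Pam3CSK4-labelled libraries carry the letter D and the others A, B and C, so a comparison with them cannot be told apart from whatever the letter stands for.

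**Figure D1:**
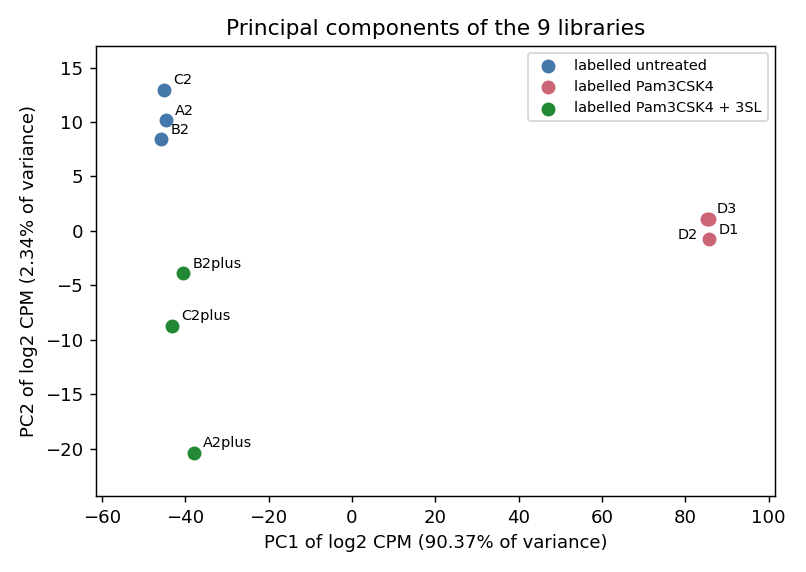
Principal components of the log2 CPM of the 9 libraries, 1 point per library, coloured by labelled group; the horizontal axis holds 90.4% and the vertical axis 2.34% of the variance. The 3 Pam3CSK4-labelled libraries lie between 85.3 and 85.7 on the horizontal axis and the other 6 between -45.7 and -37.8; on the vertical axis A2plus lies at -20.4, apart from C2plus at -8.70 and B2plus at -3.91.

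Against the untreated-labelled libraries, the Pam3CSK4-labelled libraries had far lower levels of inflammatory cytokine, enzyme and interferon-stimulated genes and higher levels of cell cycle genes. Il1b (ENSMUSG00000027398; chromosome 2, 129364570 to 129371139 on GRCm38) was 1680-fold lower. Tnf (ENSMUSG00000024401; chromosome 17, 35199381 to 35202007), which encodes tumor necrosis factor, was 93.0-fold lower, at 18.4 ± 0.67 CPM against 1704 ± 46.0 CPM (SD, n = 3 each). Ccnd1 (ENSMUSG00000070348; chromosome 7, 144929931 to 144939925), which encodes cyclin D1, was 26.9-fold higher, at 540 ± 27.8 CPM against 20.2 ± 0.928 CPM (SD, n = 3 each). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p was 3.2e-35 for Il1b, 3.2e-35 for Tnf and 8.62e-30 for Ccnd1.

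All 23 tested cytokine and chemokine genes were lower, and all 23 also adjusted over the list alone (median log2 change -6.63). Il1a was 1350-fold lower, Cxcl3 1327-fold and Ccl2, a monocyte chemoattractant, 4.36-fold. The log2 change of Cxcl3 was -10.37, and -11.24 without D3. Il6 (ENSMUSG00000025746; chromosome 5, 30013114 to 30019981) fell from 359 ± 26.1 CPM in the untreated-labelled libraries to 3 counts in all 3 Pam3CSK4-labelled libraries together, a ratio with a counting interval of 1803 to 25550. Csf3 was left with 1 count, with an interval of 873 to 192100. With any list member that had no count in a group set to 3 counts there, the list's median was -6.54. Of the NF-κB pathway and its feedback inhibitors all 23 were lower (23 adjusted over the list alone; median -3.80), with Socs3 704-fold and Nfkbia 24.8-fold lower. Of 24 inflammatory enzymes and effectors 23 were lower and 1, Plau, which encodes urokinase, was 36.1-fold higher (23 and 1 adjusted over the list alone). Among them Ptgs2, the inducible cyclooxygenase, was 1092-fold lower, Acod1, which makes itaconate, 798-fold, and Nos2, the inducible nitric oxide synthase, 650-fold. Nos2 stood at only 0.24, 0.115 and 0.382 CPM in D1, D2 and D3. Its log2 change was -9.35, or -8.72 when thinned to equal depth and -9.80 to -8.93 without 1 library. All 34 interferon-stimulated genes were lower (34 adjusted over the list alone), with Gbp5 155-fold and Gbp2 32.7-fold lower, although reads of these related guanylate-binding protein genes may be divided between copies. These 4 lists were called lower by camera with the preset correlation, with Benjamini-Hochberg adjusted p of 1.98e-21 for cytokines, 1.52e-21 for NF-κB, 1.52e-21 for enzymes and 1.32e-18 for interferon-stimulated genes. With an estimated correlation the adjusted p was 0.158, 0.130, 0.130 and 0.205 in the same order.

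Of 20 Toll-like receptor sensing genes 14 were lower and 3, Tlr4, Tlr9 and Irak1, were higher (14 and 3 adjusted over the list alone). Tlr2, the receptor subunit for bacterial lipopeptides, was 22.9-fold lower, at 52.5 ± 1.80 CPM against 1198 ± 12.3 CPM (SD, n = 3 each), and Cd14 10.6-fold lower. Of 17 immediate-early transcription factors 13 were lower, among them Ier3 (24.6-fold) and Junb (11.3-fold), and Jun, Myc and Klf2 were higher (13 and 3 adjusted over the list alone). Of 13 genes of MHC class II presentation and costimulation 10 were lower and 0 higher (10 adjusted over the list alone), led by Cd40 at 37.1-fold and Cd274 at 21.4-fold; without D3 1 was higher. Of 22 glycolysis and hypoxia genes 20 were lower and Hk3 was higher (20 and 1 adjusted over the list alone), with the kinase gene Pfkfb3 8.87-fold and the lactate exporter gene Slc16a3 7.45-fold lower. Of 17 NRF2 antioxidant genes 14 were lower and Gclc and Taldo1 were higher (14 and 2 adjusted over the list alone), with the cystine transporter gene Slc7a11 141-fold and Txnrd1 3.44-fold lower, and 1 was higher without A2 or D1. Camera with the preset correlation called these 5 lists lower at Benjamini-Hochberg adjusted p of 4.19e-05, 0.00184, 0.00184, 5.65e-12 and 5.91e-06 in that order, and the adjusted p was 0.130, 0.301, 0.147, 0.130 and 0.130 with an estimated correlation.

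Cell cycle genes were higher: 26 of 27, and 26 adjusted over the list alone, with a median of 1.35. Mcm6, a subunit of the replicative helicase, was 10.9-fold higher. Camera gave a Benjamini-Hochberg adjusted p of 2.75e-14, and the adjusted p was 0.158 with an estimated correlation. Of 24 cholesterol synthesis genes and SREBP2 targets 18 were higher (18 adjusted over the list alone), Dhcr7 by 5.41-fold and Msmo1 by 1.84-fold, while 3 were lower, among them Hsd17b7 and Srebf2. The list's camera adjusted p by Benjamini-Hochberg was 0.0110, it was 0.0703 without B2, and the adjusted p was 0.643 with an estimated correlation. Of 25 lysosome genes 16 were higher (17 adjusted over the list alone), with Atp6v0d2, a proton pump subunit gene, at 4.01-fold and Gpnmb at 1.66-fold, and Ctsz, Atp6v0d1, Atp6v1h, Atp6ap1 and Tfe3 were lower. That list's camera adjusted p by Benjamini-Hochberg was 0.0451, was 0.643 with an estimated correlation, and lay between 0.0550 and 0.107 without A2, B2, C2, D1 or D2 and at 0.0622 with DESeq2 size factors.

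The single genes with the largest rises in the Pam3CSK4-labelled libraries were Nanos1 (64.5-fold), Rgs2, a regulator of G protein signalling (47.1-fold), Plau, Rnf144b (28.9-fold), Cdca7l (27.9-fold), Ccnd1, the costimulatory receptor gene Cd28 (26.5-fold) and Rnf150 (23.6-fold). By the fitted fold, those with the largest falls were Il6, Csf3, Il1b, Il1a, Cxcl3, Shisa3, Ptgs2 and Serpinb2 (902-fold lower). Shisa3 had 1 count in the 3 Pam3CSK4-labelled libraries, with an interval of the ratio of 318 to 69990. That interval starts below the fold of Acod1 given above, so the place of Shisa3 among these genes is not settled.

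Lipid-handling genes moved both ways and their lists were not called. Of 20 liver X receptor targets 11 were higher and 5 lower (11 and 5 adjusted over the list alone; camera Benjamini-Hochberg adjusted p = 0.381). The lower ones were Abca1, which exports cholesterol (7.70-fold), Nr1h3, the receptor LXRα itself (5.21-fold), Mylip (1.67-fold), Lpcat3 and Nr1h2. Of 21 genes of lipid uptake, storage and handling 11 were higher and 7 lower (11 and 7 adjusted over the list alone; camera Benjamini-Hochberg adjusted p = 0.193), with Nceh1, a cholesterol ester hydrolase gene, 9.08-fold higher and Olr1, a scavenger receptor gene, 73.9-fold lower. The list's median was 0.35 and its mean -0.02. Of 24 sialic acid receptor and enzyme genes 13 were higher and 8 lower (13 and 8 adjusted over the list alone; camera Benjamini-Hochberg adjusted p = 0.815; median 0.19, mean -0.19), with the inhibitory receptor gene Siglece 54.7-fold and the sialyltransferase gene St3gal1 5.33-fold lower. Of 18 anti-inflammatory and alternative-activation genes 7 were higher and 9 lower (7 and 10 adjusted over the list alone; camera Benjamini-Hochberg adjusted p = 0.812), with the mannose receptor gene Mrc1 2.41-fold higher and Il1rn 5.86-fold lower. Of 19 unfolded protein and integrated stress response genes 7 were higher and 6 lower (7 and 6 adjusted over the list alone; camera Benjamini-Hochberg adjusted p = 0.958; median 0.02, mean -0.11), Ppp1r15a by 4.72-fold and Herpud1 by 2.92-fold lower, against 13 higher and 5 lower with library size only. Of 24 nuclear-encoded oxidative phosphorylation genes 6 were higher and 11 lower, against 20 higher and 1 lower with library size only, so no direction is given (6 and 11 adjusted over the list alone; camera Benjamini-Hochberg adjusted p = 0.797). Cox5a was 1.33-fold lower and Atp5b 1.22-fold lower, the latter turning to a log2 change of 0.02 with library size only.

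Markers of macrophages and of other cells were measured beside these groups. Of 18 macrophage identity genes 5 (among them Cd68, Mertk, C1qc and Trem2) were higher and 10 lower, against 10 and 5 with library size only (5 and 10 adjusted over the list alone; camera Benjamini-Hochberg adjusted p = 0.520). Of 14 neutrophil and progenitor markers 5 (Elane, Mpo, Prtn3, Retnlg and Mmp8) were higher and 7 lower (5 and 7 adjusted over the list alone; camera Benjamini-Hochberg adjusted p = 0.818), with 3 higher without B2, and 7 higher and 5 lower with library size only. Of 9 dendritic cell markers 7 were lower and Batf3 was higher (7 and 1 adjusted over the list alone), although 0 were higher without D1. Camera gave that list a Benjamini-Hochberg adjusted p of 0.0298, it lay between 0.0504 and 0.107 without B2, C2, D1 or D3, and the adjusted p was 0.205 with an estimated correlation. Few members of the remaining marker lists were tested: 2 lymphocyte markers with Cd4 higher, 3 stromal markers with Pdgfrb lower, and 1 erythroid and mast cell marker, Kit, which was higher. The camera Benjamini-Hochberg adjusted p of these was 0.897, 0.520 and 0.812. The list alone gave the same 3 calls, but 0 lymphocyte markers were higher without B2, D2 or D3, 1 was lower without these or A2, D1, A2plus or C2plus, and without B2 Kit was not called and 2 stromal markers were lower. Of 11 mitochondrially encoded messenger RNAs 7 were lower (7 adjusted over the list alone; camera Benjamini-Hochberg adjusted p = 0.596), but with library size only 7 were higher, with the GC and length offsets 2 were higher and 0 lower, and without C2 4 were lower. They made up 1.03% to 1.26% of counts in all libraries.

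In all, 8597 of 11469 genes passed edgeR's quasi-likelihood test, 4474 higher and 4123 lower in the Pam3CSK4-labelled libraries, of which 2750 differed at least 2-fold (1510 higher, 1240 lower). With library size only the median gene moved by 0.34 on the log2 scale and 74.3% of the called genes were higher, against 52.0% with TMM factors. The 2 groups did not overlap for 76.0% of genes, where chance gives 10%. Camera with the preset correlation called 13 of 25 lists, fry 22, and camera with an estimated correlation 0, with 7 at an unadjusted p under 0.05.

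**Figure D2:**
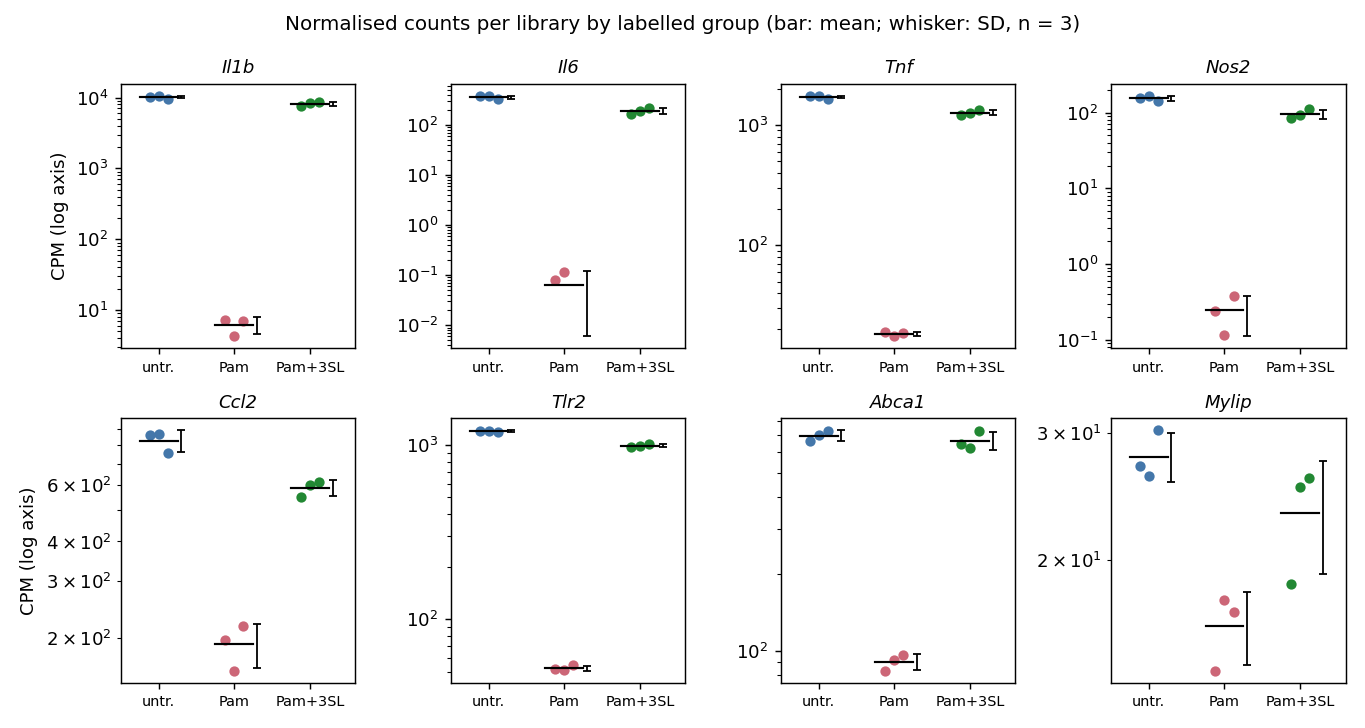
CPM of Il1b, Il6, Tnf, Nos2, Ccl2, Tlr2, Abca1 and Mylip on log axes, 1 point per library, by labelled group; bars are means and whiskers SD over 3 libraries. The D3 library had no Il6 count and is not drawn. The Pam3CSK4-labelled libraries lie below both other groups for Il1b (6.23 against 10160 and 8136 CPM) and for Abca1 (90.4 against 698 and 667 CPM).

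Adding 3SL to Pam3CSK4, as labelled, went with high inflammatory genes: Il1b was 1345-fold and Tnf 69.2-fold higher in the 3SL-labelled than in the Pam3CSK4-labelled libraries. Tnf stood at 1267 ± 58.2 CPM (SD, n = 3). Cell cycle genes were lower, with Ccnd1 20.8-fold lower at 26.4 ± 4.83 CPM (SD, n = 3) and Mcm6, at a log2 change of -3.46, lower too. As labelled, the comparison asks how 3SL alters the response to Pam3CSK4. Were the names of the untreated and Pam3CSK4 groups exchanged, it would instead set cells with both compounds against untreated cells. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p was 8.94e-35 for Il1b, 1.14e-34 for Tnf and 2.57e-28 for Ccnd1.

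All 23 cytokine genes were higher (23 adjusted over the list alone), with Il1a at 864-fold and Ccl2 at 3.10-fold. The list's median was 6.28, or 6.11 with any member that had no count in a group set to 3 counts there. The ratio for Il6 had a counting interval of 953 to 13520 and that for Csf3 one of 817 to 179900. All 23 NF-κB pathway genes were higher (23 adjusted over the list alone), Socs3 by 689-fold and Nfkbia by 23.8-fold. So were 23 of 24 enzymes and effectors (23 adjusted over the list alone), while Plau was 32.4-fold lower. Saa3 was higher by 788-fold, Ptgs2 by 782-fold, Acod1 by 636-fold and Nos2 by 403-fold. The log2 change of Nos2 was 8.65, or 8.05 when thinned to equal depth and 8.24 to 9.11 without 1 library. Of 20 Toll-like receptor sensing genes 14 were higher, Tlr2 by 18.9-fold and Cd14 by 9.64-fold, and Tlr4, Tlr7, Tlr9 and Irak1 were lower (14 and 4 adjusted over the list alone). Of 22 glycolysis genes 20 were higher, Pfkfb3 by 8.98-fold, and Hk3 was lower (20 and 1 adjusted over the list alone). Of 17 NRF2 genes 15 were higher, Slc7a11 by 141-fold, and Gclc was lower (15 and 1 adjusted over the list alone). All 27 cell cycle genes were lower (27 adjusted over the list alone; median -1.34). Camera with the preset correlation gave Benjamini-Hochberg adjusted p of 3.58e-62 for cytokines, 8.51e-70 for NF-κB, 8.81e-89 for enzymes, 5.17e-07 for receptors, 1.65e-16 for glycolysis, 1.39e-11 for NRF2 and 9.46e-20 for the cell cycle. The same 7 lists were called with an estimated correlation, at adjusted p between 0.0112 and 0.0435.

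All 34 interferon-stimulated genes were higher (34 adjusted over the list alone), Gbp5 by 98.8-fold, at a camera Benjamini-Hochberg adjusted p of 1.18e-16 and an adjusted p of 0.208 with an estimated correlation. Of 17 immediate-early factors 12 were higher, Ier3 by 23.3-fold, and Jun and Klf2 were lower (12 and 2 adjusted over the list alone), at a camera Benjamini-Hochberg adjusted p of 3.63e-04 and an adjusted p of 0.198 with an estimated correlation. Of 13 MHC class II and costimulation genes 10 were higher (10 adjusted over the list alone), Cd40 by 30.5-fold, at a camera Benjamini-Hochberg adjusted p of 0.00476 and an adjusted p of 0.0522 with an estimated correlation; with library size only 6 were higher, and 1 was lower without D3 or B2plus. Of 25 lysosome genes 18 were lower (18 lower and 5 higher adjusted over the list alone), Atp6v0d2 by 4.44-fold and Gpnmb by 1.77-fold, and Ctsz, Atp6v0d1, Atp6v1h, Atp6ap1 and Tfe3 were higher, at a camera Benjamini-Hochberg adjusted p of 0.0145 and an adjusted p of 0.644 with an estimated correlation.

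The 8 genes with the largest falls in the 3SL-labelled libraries were Nanos1 (53.7-fold), Rgs2 (46.5-fold), Plau, Cd28 (29.7-fold), Hmga2 (27.1-fold), Rnf144b (26.2-fold), Cdca7l (25.8-fold) and the chemokine receptor gene Cxcr4 (25.4-fold). By the fitted fold, the largest rises were those of Csf3, Il6, Il1b, Shisa3, Il1a, Saa3, Ptgs2 and Socs3. Shisa3 had a counting interval of the ratio of 242 to 53530. It starts below the fold of Acod1 given above for this comparison, so the place of Shisa3 is not settled.

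Cholesterol synthesis genes were not called as a list (camera Benjamini-Hochberg adjusted p = 0.699), with 12 of 24 higher and 5 lower (12 and 5 adjusted over the list alone), against 8 and 9 with library size only. Dhcr7 was 3.16-fold lower, and Tm7sf2, Msmo1, Insig1 and Stard4 were lower too. Of 20 liver X receptor targets 7 were higher, Abca1 by 7.37-fold, Nr1h3 by 4.61-fold and Mylip by 1.45-fold, and 11 lower (7 and 11 adjusted over the list alone; camera Benjamini-Hochberg adjusted p = 0.886). Of 21 lipid-handling genes 6 were higher and 11 lower, Nceh1 by 9.03-fold and the lysosomal acid lipase gene Lipa by 2.38-fold (6 and 11 adjusted over the list alone; median -0.35, mean 0.01; camera Benjamini-Hochberg adjusted p = 0.0561, or 0.0428 without D1 and 0.0125 with library size only). Of 24 sialic acid genes 6 were higher, Siglece by 51.8-fold and St3gal1 by 4.62-fold, and 12 lower (6 and 12 adjusted over the list alone; median -0.34, mean 0.04; camera Benjamini-Hochberg adjusted p = 0.913). Of 18 anti-inflammatory genes 10 were higher, Il1rn by 5.33-fold, and 7 lower, Mrc1 by 2.42-fold, against 8 and 9 with library size only (10 and 8 adjusted over the list alone; camera Benjamini-Hochberg adjusted p = 0.886). Of 19 unfolded protein response genes 10 were higher, Ppp1r15a by 4.02-fold and Herpud1 by 3.02-fold, and 5 lower, Ddit3, Dnajb9, Sdf2l1, Psat1 and Pdia4; with library size only 4 were higher and 10 lower (10 and 5 adjusted over the list alone; camera Benjamini-Hochberg adjusted p = 0.834). Of 24 oxidative phosphorylation genes 7 were higher and 6 lower (6 and 6 adjusted over the list alone), against 0 and 19 with library size only, so no direction is given (camera Benjamini-Hochberg adjusted p = 0.886). Sdha was 1.23-fold lower, and Cox5a was 1.28-fold higher, with a log2 change of 0.09 that was not called with library size only (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.0702).

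Among markers, 10 of 18 macrophage identity genes were higher and 7 lower, or 6 higher with library size only (10 and 7 adjusted over the list alone; camera Benjamini-Hochberg adjusted p = 0.774). Of 9 dendritic cell markers 7 were higher and Batf3 was lower (7 and 1 adjusted over the list alone; camera Benjamini-Hochberg adjusted p = 0.170), and 0 were lower without D1 or C2plus. Of 14 neutrophil markers S100a8, S100a9, Ngp, Camp and Chil1 were higher and Elane, Mpo, Prtn3, Retnlg and Mmp8 lower (5 and 5 adjusted over the list alone; camera Benjamini-Hochberg adjusted p = 0.886). Cd4 and Kit were lower and Pdgfrb was higher, each the only called member of its list, also adjusted over the list alone (camera Benjamini-Hochberg adjusted p = 0.886 for each). Cd4 was not called lower without D2, D3, B2plus or C2plus, nor Kit without B2plus, where 0 markers of their lists were lower; 1 lymphocyte marker was higher without D3 or C2plus. Of 11 mitochondrially encoded messenger RNAs mt-Nd5, mt-Nd6 and mt-Co1 were higher and mt-Cytb was lower, against 0 higher and 8 lower with library size only and 0 and 3 with the GC and length offsets (3 and 1 adjusted over the list alone; camera Benjamini-Hochberg adjusted p = 0.886). The number lower was 0 without D2 or A2plus and 2 without C2plus.

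A total of 8204 genes passed edgeR's quasi-likelihood test, 3978 higher and 4226 lower in the 3SL-labelled libraries, of which 2640 differed at least 2-fold (1207 higher, 1433 lower). With library size only the median gene moved by -0.29 on the log2 scale and 27.6% of the called genes were higher, against 48.5%. Camera with the preset correlation called 11 of 25 lists, camera with an estimated correlation 7 and fry 20.

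Cells with both compounds, as labelled, differed from the untreated-labelled cells by smaller amounts: cholesterol synthesis genes were higher and cytokine and interferon-stimulated genes lower. The interferon-stimulated list was not called by camera with an estimated correlation (Benjamini-Hochberg adjusted p = 0.0613). Were the names of the untreated and Pam3CSK4 groups exchanged, this comparison would measure what 3SL changed in the presence of Pam3CSK4. Scd2, a stearoyl-CoA desaturase gene (ENSMUSG00000025203; chromosome 19, 44293674 to 44306864), was 2.99-fold higher at 163 ± 8.97 CPM against 54.9 ± 11.6 CPM (SD, n = 3 each). Lss (ENSMUSG00000033105; chromosome 10, 76531588 to 76557138), which encodes lanosterol synthase, was higher at 46.9 ± 5.67 CPM against 23.2 ± 2.56 CPM (SD, n = 3 each). Cxcl3 (ENSMUSG00000029379; chromosome 5, 90786103 to 90789600), a neutrophil chemoattractant gene, was 2.15-fold lower at 535 ± 56.4 CPM against 1153 ± 46.8 CPM (SD, n = 3 each). Il6 was 1.87-fold lower at 192 ± 24.3 CPM (SD, n = 3). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p was 2.63e-13 for Scd2, 3.38e-09 for Lss, 3.75e-13 for Cxcl3 and 2.55e-11 for Il6.

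Of 24 cholesterol synthesis genes and SREBP2 targets 22 were higher and 0 lower (23 adjusted over the list alone), with a median log2 change of 0.69. Acat2 was 1.94-fold higher, Cyp51, the lanosterol demethylase gene, 1.80-fold, and Msmo1 1.67-fold, and the 2 not called were Tm7sf2 (0.27) and Ebp (0.17). Camera gave a Benjamini-Hochberg adjusted p of 2.54e-108 with the preset correlation and 0.00573 with an estimated one. Lrp8, a lipoprotein receptor gene, was 1.88-fold higher. The 20 liver X receptor targets were divided, with Srebf1, Scd2, Fasn, which encodes fatty acid synthase (1.73-fold), and Acaca higher and Abcg1, Nr1h3 and Tgm2 lower (7 and 3 adjusted over the list alone). Abca1 (log2 change -0.06 ± 0.0459 SE) and Mylip (-0.21 ± 0.0985 SE) were not called. For these 2 genes edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave an adjusted p of 0.470 and 0.215, and Abca1 was called at -0.13 and 0.0214 with the GC and length offsets. The list was called higher by camera (Benjamini-Hochberg adjusted p = 0.00235, or 0.149 with an estimated correlation and 0.0501 with no filter on low counts), and without A2, B2, A2plus or B2plus 2 members were higher, with 1 lower without B2 or B2plus. Of 21 lipid-handling genes 2 were higher, among them Scarb1, and Olr1 (1.45-fold), Fabp4, Fabp5 and Lipa were lower (2 and 5 adjusted over the list alone; camera Benjamini-Hochberg adjusted p = 0.935), with 1 lower without B2 or A2plus.

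Of 23 cytokine and chemokine genes 20 were lower and 0 higher (20 adjusted over the list alone), with a median of -0.47. Cxcl1 was 1.72-fold, Ccl2 1.41-fold and Tnf 1.34-fold lower. Il1b had a log2 change of -0.32, and Csf2 (-0.43), Csf3 (-0.08) and Tnfsf9 (-0.16) were not called. For the list, camera gave a Benjamini-Hochberg adjusted p of 2.75e-72, and 0.00802 with an estimated correlation. For Il1b, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave an adjusted p of 1.23e-05, DESeq2 gave 0.280 and robust quasi-likelihood 0.0597. For Ccl2 edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave 6.59e-06 and its robust form 0.0575. Of 24 enzymes and effectors 14 were lower (17 adjusted over the list alone), Nos2 by 1.61-fold and Clec4e, a receptor for mycobacterial glycolipid, by 1.40-fold, while the protease gene Mmp9 was 1.47-fold higher. Camera's Benjamini-Hochberg adjusted p for that list was 1.44e-18, and 0.0156 with an estimated correlation.

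Of 34 interferon-stimulated genes 29 were lower and 0 higher (33 adjusted over the list alone), with a median of -0.37 and with Gbp5 and Gbp3 both 1.57-fold lower. With robust quasi-likelihood 7 were lower. As a list they had a camera Benjamini-Hochberg adjusted p of 1.25e-33, and the adjusted p was 0.0613 with an estimated correlation. The 7 lower genes among 20 of Toll-like receptor sensing were Tlr2 (1.21-fold), Tlr3, Tlr7 (1.32-fold), Tlr8, Cd14, Irak2 and Ticam2 (7 adjusted over the list alone), and 4 were lower without B2, A2plus or B2plus. Their camera Benjamini-Hochberg adjusted p was 7.04e-06, and 0.0102 with an estimated correlation. Among 13 MHC class II and costimulation genes H2-Ab1 (1.36-fold), Cd40, Cd83 (1.45-fold) and Cd274 were lower (8 adjusted over the list alone), at a camera Benjamini-Hochberg adjusted p of 1.63e-06, and 0.0102 with an estimated correlation. Within the 23 NF-κB genes the phosphatase genes Dusp1 (log2 change 0.32) and Dusp2 and Zfp36, which destabilizes cytokine messenger RNA, were higher, and Traf1 (-0.32), Nfkb1, Nfkb2, Nfkbib, Nfkbie and Tnfaip3 were lower (5 and 10 adjusted over the list alone). Without A2 or A2plus 3 were lower, without A2 1 was higher, and with library size only 4 were higher and 3 lower. Camera's Benjamini-Hochberg adjusted p was 0.0250, it was 0.112 without B2, 0.0981 without A2plus and 0.168 with library size only, and the adjusted p was 0.333 with an estimated correlation. Of 17 immediate-early factors Fos was 1.40-fold higher and 6 were lower, Klf6 by 1.12-fold and Klf2 by 1.82-fold, with Fosl2, Junb, Jund and Egr2 (1 and 8 adjusted over the list alone). Without B2 3 of them were lower, and the fall of Klf2 was not called there (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.0952). Camera gave the list a Benjamini-Hochberg adjusted p of 0.00498, and the adjusted p was 0.189 with an estimated correlation.

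Of 17 NRF2 antioxidant genes 10 were higher and 0 lower (12 adjusted over the list alone), with Gclm, a glutathione synthesis gene, 1.33-fold and Hmox1, which encodes heme oxygenase, 1.32-fold higher. The NRF2 list had a camera Benjamini-Hochberg adjusted p of 3.56e-13, and 0.00802 with an estimated correlation. Of 19 unfolded protein response genes 7 were higher, the endoplasmic reticulum chaperone and folding genes Pdia4 (1.29-fold), Hyou1 (1.26-fold), Hspa5, Dnajb11, Sdf2l1, Calr and Manf, and Atf4 and Ppp1r15a were lower (8 and 2 adjusted over the list alone), with 1 lower without A2 or C2plus and 0 without B2 or A2plus. Camera's Benjamini-Hochberg adjusted p was 2.39e-05, and 0.0435 with an estimated correlation.

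Of 24 sialic acid receptor and enzyme genes 6 were lower and 0 higher (7 adjusted over the list alone): St3gal3 (1.38-fold), St3gal1, Lgals3 (1.15-fold), Neu1, Cd33 and Siglech. Camera's Benjamini-Hochberg adjusted p was 0.00116, and 0.0300 with an estimated correlation. Of 25 lysosome genes the cathepsin genes Ctsl (1.11-fold), Ctsz (1.10-fold) and Ctsb, with Neu1 and Gpnmb, were lower (8 adjusted over the list alone), at a camera Benjamini-Hochberg adjusted p of 2.49e-04 and an adjusted p of 0.333 with an estimated correlation; limma-voom called 9 lower, and 3 were lower without B2 or A2plus. Of 18 anti-inflammatory genes Il4ra (1.19-fold) and Stab1 were higher and Chil3 (1.21-fold), Il1rn and Ccl17 lower (2 and 4 adjusted over the list alone; camera Benjamini-Hochberg adjusted p = 0.422). Of 22 glycolysis genes Pkm (1.08-fold) and Pdk1 were higher and Hk3 and Hif1a lower (3 and 2 adjusted over the list alone; camera Benjamini-Hochberg adjusted p = 0.781), with 1 higher without A2, B2, A2plus or B2plus and at most 1 lower without any of the 9 libraries but C2plus. The 1.08-fold lower level of Hk3 was not called without B2, C2, A2plus or B2plus, where edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave adjusted p between 0.0571 and 0.168, nor with library size only (0.146), with only the 2 groups compared (0.0514) or thinned to equal depth (0.0653). Of 27 cell cycle genes only Ccnd1 was called (log2 change 0.38; 1 adjusted over the list alone; camera Benjamini-Hochberg adjusted p = 0.367), and without B2 or A2plus edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave it 0.0663 and 0.0839. The log2 change of Mcm4, 0.23 ± 0.0817 SE, was not called, although it was without A2 or C2plus and with library size only, where 2 cell cycle genes were higher. By edgeR's quasi-likelihood test 0 of 24 oxidative phosphorylation genes were called, 3 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. Camera gave that list a Benjamini-Hochberg adjusted p of 0.195, or 0.0335 without C2, 0.0412 without B2plus and 0.0350 with no filter on low counts. Its members Cox7a2 and Cox4i1 had log2 changes of -0.13 ± 0.0472 and -0.11 ± 0.0411 (SE), the first called without C2 and the second without B2plus and with no filter on low counts.

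The largest single fall was that of Lyz1 (log2 change -3.02 ± 0.571 SE), a lysozyme gene nearly identical in sequence to Lyz2, with which it may share reads. It rested on A2, without which it was -1.68, at 195 CPM against 43.4 in B2 and 17.6 in C2, and stood between 10.4 and 10.9 CPM in the 3SL-labelled libraries. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment its adjusted p was 6.33e-04, with limma-voom 0.0630 and with robust quasi-likelihood 0.199. Other large falls were those of the adhesion receptor gene Adgre4 (1.99-fold), the fatty acid-binding protein gene Fabp3 (1.82-fold), Ccrl2 (1.78-fold) and Cd200 (1.74-fold), and other large rises those of E2f2 (1.87-fold), Nxpe5 (1.86-fold) and Utp14b (1.80-fold). For E2f2, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave 0.00591, and 0.0831 without B2plus.

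Among markers, 3 of 18 macrophage identity genes were higher, among them Csf1r and Itgam, and Cd68, Mpeg1 and Adgre4 were lower (4 and 4 adjusted over the list alone; camera Benjamini-Hochberg adjusted p = 0.422); 1 was lower without C2, 1 was higher without A2plus, and with library size only 5 were higher and 1 lower. Of 14 neutrophil markers S100a8, S100a9 and Lyz1 were lower (7 adjusted over the list alone), at a camera Benjamini-Hochberg adjusted p of 8.64e-04 and an adjusted p of 0.189 with an estimated correlation; robust quasi-likelihood called 1, and 5 were lower without D3. Of 9 dendritic cell markers Bst2 was lower (2 adjusted over the list alone, and 2 without A2), at a camera Benjamini-Hochberg adjusted p of 0.0323, 0.100 without B2, and an adjusted p of 0.181 with an estimated correlation. Of 11 mitochondrially encoded messenger RNAs mt-Nd1 and mt-Cytb were lower (4 adjusted over the list alone), at a camera Benjamini-Hochberg adjusted p of 0.0167, 0.178 without C2, and an adjusted p of 0.357 with an estimated correlation; 4 were lower without B2 and 1 without C2. The stromal marker Pdgfrb was lower, with 0 stromal markers called without B2 or A2plus (1 adjusted over the list alone; camera Benjamini-Hochberg adjusted p = 0.382). Of 2 lymphocyte markers and 1 erythroid marker 0 were called by edgeR's quasi-likelihood test, 0 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0 (0 adjusted over the list alone; camera Benjamini-Hochberg adjusted p = 0.628 and 0.850).

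A total of 1025 genes passed edgeR's quasi-likelihood test, 439 higher and 586 lower in the 3SL-labelled libraries, with a median absolute log2 change of 0.26, and 20 differed at least 2-fold (13 higher, 7 lower). The groups did not overlap for 23.97% of genes, where chance gives 10%. Without B2, the deepest library, 626 genes were called (270 higher, 356 lower), and without A2plus 683 were, 377 of them lower. With library size only 66.0% of the called genes were higher, against 42.8%, and DESeq2 called 282 higher. Camera with the preset correlation called 16 of 25 lists, camera with an estimated correlation 8 and fry 14.

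**Figure D3:**
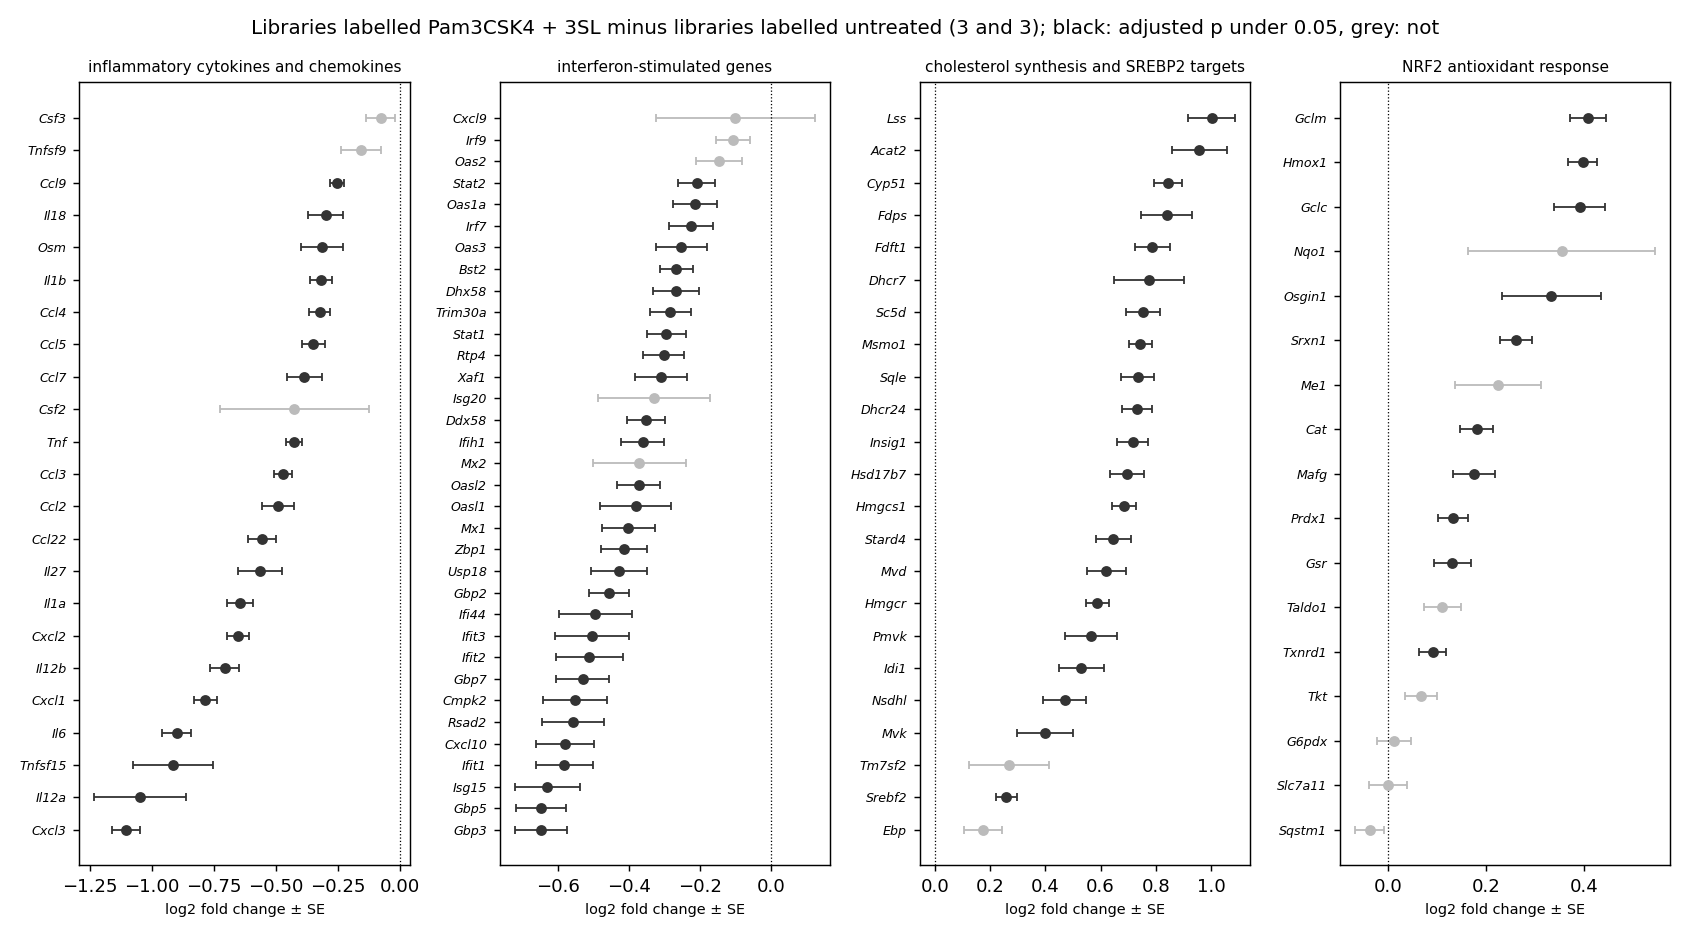
Log2 change ± SE of the tested members of 4 gene lists, 3SL-labelled minus untreated-labelled libraries (3 and 3), black where edgeR's quasi-likelihood test called the gene and grey where it did not; 1 called member of the cholesterol synthesis list is not drawn. Of the cytokine genes 20 of 23 and of the interferon-stimulated genes 29 of 34 were called lower, and of the cholesterol synthesis genes 22 of 24 and of the NRF2 genes 10 of 17 were called higher.

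**Figure D4:**
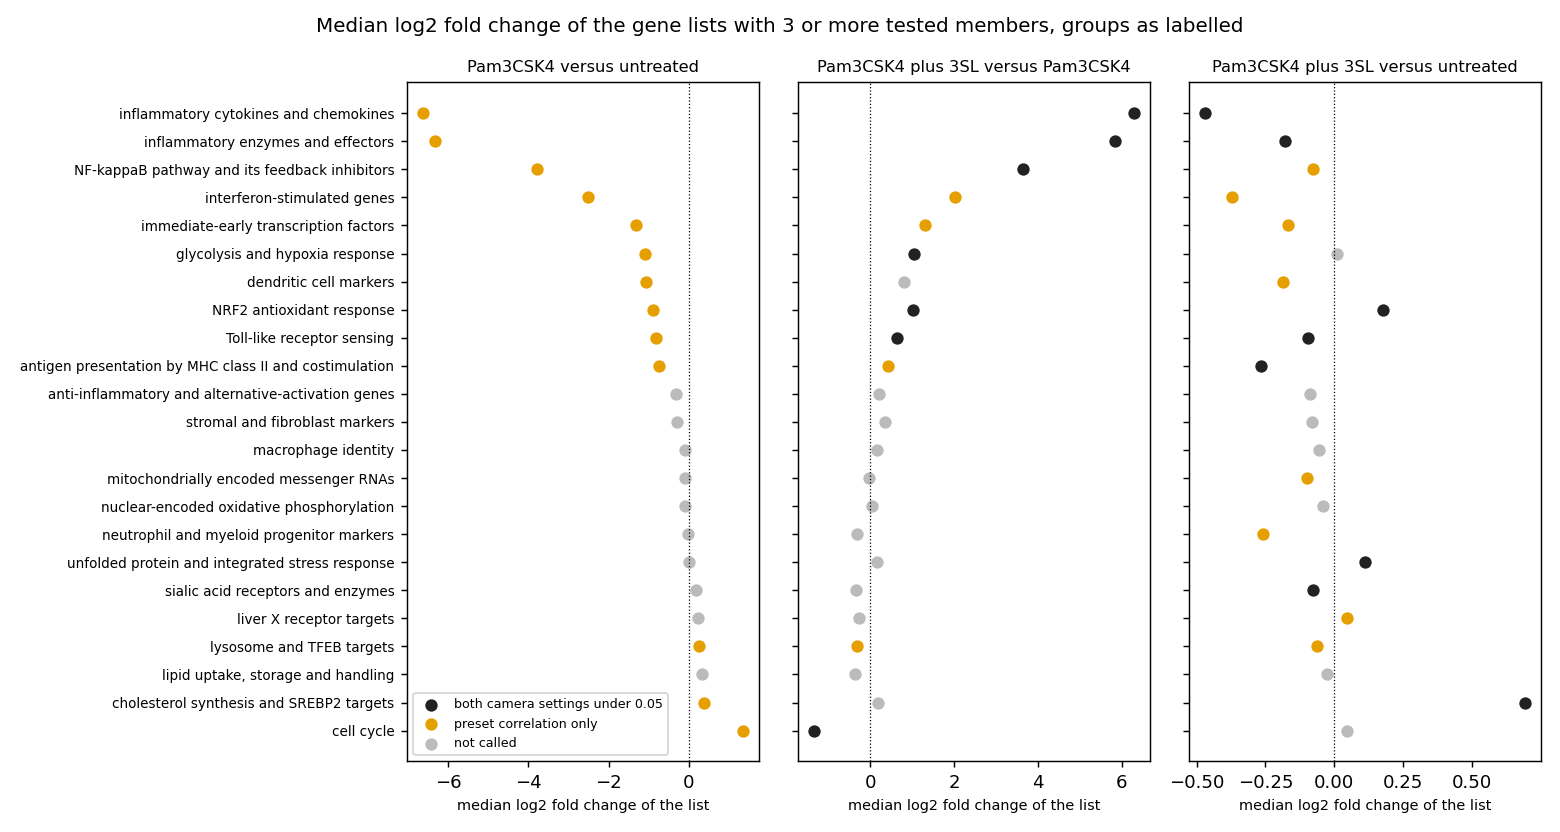
Median log2 change of each gene list with 3 or more tested members in the 3 comparisons, groups as labelled; black marks lists called by camera with both correlations, orange those called with the preset correlation only, grey those not called. The cytokine list lies at -6.63, 6.28 and -0.47 and the cholesterol synthesis list at 0.40, 0.20 and 0.69 in the 3 panels, whose horizontal axes differ in range.

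The genes that differed between the Pam3CSK4-labelled and untreated-labelled libraries differed the opposite way between the 3SL-labelled and Pam3CSK4-labelled libraries. Of 1510 genes at least 2-fold higher in the first comparison 1476 were called lower and 0 higher in the second, with a median log2 change of -1.47, and of 1240 genes at least 2-fold lower 1219 were called higher and 0 lower, with a median of 1.83. Across 11469 genes, which are not independent, the fold changes had a Pearson correlation of -0.983 and a covariance of -1.60. Both comparisons share the Pam3CSK4-labelled libraries, which alone gave a correlation of -0.477 and a covariance of -0.0095 in simulated data without effects. With the 3SL-labelled libraries drawn at the Pam3CSK4-labelled level, the simulated values were -0.0492 and -0.0120. Measured against 1 Pam3CSK4-labelled library left out of the first comparison, the correlation was -0.954, -0.957 and -0.953 for D1, D2 and D3, and 1403, 1421 and 1419 genes were lower. Genes higher and then lower numbered 3981, against 1649 for independent lists, and those lower and then higher 3681, against 1430.

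Of the genes that separated the untreated-labelled from the Pam3CSK4-labelled libraries, a part also differed between the 3SL-labelled and untreated-labelled libraries; this pair was chosen after the data had been seen. Of 1240 genes at least 2-fold higher in the untreated-labelled libraries, 337 were lower and 54 higher in the 3SL-labelled ones (median log2 change -0.10), and of 1510 at least 2-fold lower, 97 were higher and 21 lower. The correlation was -0.261 and the covariance -0.0801, against -0.402 and -0.0077 in simulated data without any effect. With the 3SL-labelled libraries drawn at the untreated-labelled level, the simulated values were -0.0314 and -0.0066. With the untreated-labelled libraries split, the covariance was -0.0683, -0.0789 and -0.0753, and 144, 282 and 105 genes were lower when measured against A2, B2 and C2. Genes higher and then lower numbered 488, against 211 for independent lists, and those lower and then higher 253, against 171.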

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

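Thinning to equal depth, the offsets for GC content and length, and the pair of comparisons sharing the untreated-labelled libraries were added after the data had been seen. Of the 53 named genes of each comparison with the Pam3CSK4-labelled libraries, 53 kept direction and call under every alternative except library size only, where 52 did. There Atp5b reversed to 0.023 against the untreated-labelled libraries and Cox5a was not called between 3SL-labelled and Pam3CSK4-labelled ones. Of the 55 of 3SL-labelled against untreated-labelled libraries, between 52 and 55 did.

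With library size only, 6882 genes were higher and 2380 lower in the Pam3CSK4-labelled than in the untreated-labelled libraries, 2434 higher and 6393 lower in the 3SL-labelled than in the Pam3CSK4-labelled, and 788 higher in the 3SL-labelled than in the untreated-labelled libraries; of 2306 genes at least 2-fold higher in the first comparison 2260 were called lower in the second. These counts were made without the composition factors, and which scaling is right was not tested. In the last comparison DESeq2 called 282 genes higher, of which the cause was not tested, and an adjusted p under 0.01 left 595 genes (240 higher, 355 lower), as a stricter threshold must. Without 1 library it called 626 to 1038 genes, 270 to 435 higher and 356 to 603 lower. The untreated-labelled and 3SL-labelled libraries share letters but not deviations, with correlations of -0.017, 0.042 and 0.008, and only B2 correlated best with its own letter. With the letter as a replicate block 951 genes were called, against 984 without the block in the same 6 libraries. For the comparisons with the Pam3CSK4-labelled libraries no paired analysis was possible because these share no letter with the others.

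Camera with an estimated correlation called 0, 7 and 8 lists in the 3 comparisons, and fry called 22 and 20 in the first 2. Directions of lists reversed as follows, with the adjusted p of camera or fry by Benjamini-Hochberg; the cause was not tested. For Pam3CSK4-labelled against untreated-labelled libraries these were sialic acid genes with fry (3.77e-05), oxidative phosphorylation (0.275), unfolded protein response (0.747), sialic acid (0.900), lymphocyte (0.989) and mitochondrial (0.879) lists with library size only, and unfolded protein response (0.966) and lymphocyte (0.608) lists with no filter. For 3SL-labelled against Pam3CSK4-labelled libraries they were liver X receptor (0.436), oxidative phosphorylation (0.555) and mitochondrial (0.629) lists with fry, macrophage identity with library size only (0.930), and sialic acid (0.409) and lymphocyte (0.942) lists with no filter. For 3SL-labelled against untreated-labelled libraries they were lipid handling with library size only (0.739) and glycolysis with no filter (0.950). Without 1 library, camera's adjusted p by Benjamini-Hochberg of lists that reversed ranged in the first comparison over 0.680 to 0.972 for oxidative phosphorylation, 0.934 to 0.982 for the unfolded protein response, 0.714 to 0.982 for sialic acid and 0.871 to 0.982 for lymphocyte genes. In the last it ranged over 0.607 to 0.972 for glycolysis, 0.557 to 0.856 for the erythroid marker and 0.854 to 0.984 for lipid handling.

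The correlation of comparisons sharing the Pam3CSK4-labelled libraries was -0.954, -0.957 and -0.953 with these split, and -0.983 to -0.975 without 1 library. For those sharing the untreated-labelled libraries it was -0.180 and -0.177 measured against A2 and C2, with 144 and 105 genes lower, and -0.268 to -0.180 without 1 library. Depth limits the lowest genes: in A2plus, the shallowest library, 3 counts are 0.422 CPM.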

Other observations

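The list of fatty acid and related genes, the tests of exchanged names, scaling, restoring and mixing, the thinning and the GC and length offsets, and the lists of other tissues were chosen only after the results they bear on had been seen. Beside the cholesterol pathway, 9 of 16 genes of fatty acid and related lipid metabolism were higher in the 3SL-labelled than in the untreated-labelled libraries. The list joins genes of fatty acid synthesis, activation, elongation and desaturation with others such as Lpin1, Gpam, Aacs and Tmem97. By edgeR's quasi-likelihood test 0 were lower and 7 were not called, among them the elongation genes Elovl1 (-0.03), Hsd17b12 (-0.05) and Elovl7 (-0.46), with a median log2 change of 0.24. Among the called genes the largest changes were those of Acsl3 (0.83), which activates fatty acids, the desaturase gene Fads2 (0.79) and the elongase gene Elovl6 (0.73), followed by Acss2 (0.58), Aacs (0.41), Fads1 (0.38), Acly (0.26), Elovl5 (0.21) and Mid1ip1 (0.19). A hypothesis that the rise of cholesterol synthesis genes may extend to this list was tested with camera, which gave an unadjusted p of 1.84e-07, and 0.00808 with an estimated correlation.

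The cytokine genes were high in the libraries labelled untreated and low in those labelled Pam3CSK4, with a median log2 change of -6.63. Scaling by library composition is argued against, since the median was -6.32 with library size only. On the log2 scale the 3SL-labelled libraries lay at a median of 0.918 of the way from the Pam3CSK4-labelled to the untreated-labelled level (0.769 to 0.993 over members), where an exchange of the names of the untreated and Pam3CSK4 groups may have put them. All 23 tested NF-κB pathway genes were lower in the Pam3CSK4-labelled libraries too, although Pam3CSK4 activates Toll-like receptors. Taken as given, the labels put the high inflammatory genes in cells without that activator. That Pam3CSK4 lowers the cytokine genes and 3SL restores them cannot be told apart from an exchange of names by the median log2 change of 6.28. No group had 3SL alone. The letter D of the Pam3CSK4-labelled libraries also parts them from the letters A, B and C of all others.

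In the 3SL-labelled libraries cytokine genes were lower and cholesterol synthesis genes higher than in the untreated-labelled ones. RNA of the Pam3CSK4-labelled kind mixed into them is argued against for 12 cholesterol synthesis genes. These were called higher than in both other groups, a level no mixture of those groups reaches. The test does not cover members such as Msmo1, Acat2 and Dhcr7, whose mean levels lay between those of the other groups. With library size only, fewer members were called higher than in the Pam3CSK4-labelled libraries. For the cytokine genes, 14 members implied a median share of 32.6% of such RNA, against 9.78% over 129 other genes in none of the gene lists. Both sets were at least 8 times higher in the untreated-labelled than in the Pam3CSK4-labelled libraries, at 20 CPM or more. The central 95% of 10000 random lists of the other genes ended at 18.1%, a bound that ignores that cytokine genes move together and may be too narrow. Of 42 called members of both lists, 42 were called the same way with offsets for GC content and transcript length, and 41 with every library thinned to equal depth, which argues against either as the whole cause. A biological difference between the labelled treatments stays open and was not tested separately.

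Among the 10 splits of the 6 libraries of each comparison, 1, the real one, called as many genes as observed. It called 8597, 8204 and 1025 genes in the order of the report, and the highest other split called 0 in each by edgeR's quasi-likelihood test, with up to 115, 153 and 959 genes at an unadjusted p under 0.05. With 10 splits the share cannot fall below 0.1. Every other split mixes libraries of both labelled groups, so differences between these widen its spread. Its low counts are therefore no measure of chance.

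Transcripts typical of other tissues were present at low levels. Whether they came from other cells or from the macrophages themselves was not tested. A list of 20 hepatocyte genes summed to 43.1 CPM of unscaled totals in D2 and 51.1 in D3, against 10.7 in D1 and at most 12.3 in the other 6 libraries. Alb, the serum albumin gene, had 198 counts in D2 and 221 in D3, the latter 19.4 CPM of unscaled totals, against at most 2.14 in the other 7 libraries. A list of 16 nervous tissue genes summed to between 138 and 145 in the Pam3CSK4-labelled, 88.4 and 105 in the untreated-labelled and 111 and 139 in the 3SL-labelled libraries. Mbp, a myelin gene, alone gave 78.4 to 82.6 CPM in the Pam3CSK4-labelled and at most 51.2 in the others. Without Mbp the other 15 genes summed to between 59.4 and 66.0, 47.8 and 62.2, and 62.8 and 88.0 in the same order.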
